A study of Mus musculus with 6 samples.

How the data were processed

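RNA was sequenced from CD45-negative cells sorted from 6 YUMM1.7 tumours in C57BL/6 mice, per the labels. Of these tumours, 3 were taken before treatment and 3 during treatment with a BRAF inhibitor, and the labels call the treated tumours residual. YUMM1.7 is a mouse melanoma line that carries an activating Braf mutation. CD45, the product of Ptprc, marks leukocytes, so the sort leaves tumour cells together with fibroblasts, vessel cells and other non-leukocytes. The inhibitor, its dose and the time on treatment are not given in the sources used here. The labels number the tumours within each group, so the libraries come from separate tumours; whether each tumour came from its own mouse is not stated, and p-values measure the spread between these tumours.

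Per the labels, RNA was extracted with a QIAGEN RNeasy micro kit, and poly(A) RNA was made into unstranded TruSeq libraries. The labels describe the reads in conflicting ways, as single-end in the series text and as paired-end in the library protocol. Since the kit does not mark strand, reads of overlapping or antisense genes cannot be told apart. The authors deposited 1 table of FPKM, a count of fragments scaled by transcript length and library size, with 1 value per gene symbol and library. The submitters' processing notes name the mm9 genome, TopHat2, TopHat, Cuffnorm and Cuffdiff, without versions or roles; the gene annotation and any scaling between libraries are not given in the sources used here. The smallest FPKM values lie far below what any single read would give, so whole reads could not be recovered and the depth of each library is unknown. Intervals that need a read count are therefore not given, and an exact 0 is reported only as listed at 0. All 6 columns matched a sample by name. The series title carries 1 batch number for all libraries, and no label gives a batch or date for single libraries.

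The table held 23940 gene symbols, none repeated, of which 5880 were listed at 0 in all 6 libraries. Genes with a mean FPKM of at least 1 over the 6 libraries were tested, which left 12075. Values were taken as log2(FPKM + 0.1), and a linear model with the 2 groups was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend). Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over the genes tested, and the threshold was an adjusted p of 0.05. Fold changes are on the log2(FPKM + 0.1) scale, on BRAF inhibitor over pre-treatment, and understate the change of low genes. No count model was used, since the table holds no counts. With 3 libraries against 3, an exact permutation test cannot give a two-sided p below 0.1, so single values were tested only within the limma model.

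The design, the alternatives, the rule for naming genes and 37 gene lists were fixed before the data were examined: 23 on biology, 13 of cell type markers and 1 of immediate early genes that respond to tissue dissociation. The 32 lists with at least 3 tested genes were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation and with fry. Named genes are the 8 with the largest increase and the 8 with the largest decrease past the threshold. These had to have groups that did not overlap and a mean FPKM of at least 5 in the higher group. Predicted genes, microRNA, snoRNA and ribosomal pseudogene symbols were left out. The rule adds up to 4 members with the smallest p of each biology list, more where a list passed its test, the whole MAPK list, up to 3 of the most abundant members of each cell type or quality list, and Ptprc, Braf, Cdkn2a and Map2k1. Some genes that the rule names are not reported here. A gene named outside this rule is said to be so.

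The fit was tested on simulated data made from these libraries for the comparison of on-BRAFi with pre-treatment, in 5 simulations of 12075 genes with 200 changed. It called 11.2% of genes changed by 1 on the log2 scale, 64.4% of those changed by 2, 84.0% of those changed by 3 and 90.4% of those changed by 4. Unchanged genes made up 5.87% of the calls. The data gave 2307 changed genes, so the adjustment was stricter in the simulations, and the shares called do not give the sensitivity in the data. A shifted gene list was called in all 5 simulations, and 2 of 155 tests of unshifted lists were called. The simulated genes varied independently, whereas estimated inter-gene correlations in the data ran from -0.067 to 0.892 over the lists. The simulations therefore cannot show how often camera calls unshifted lists in these data.

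Alternatives fixed beforehand were pseudocounts of 1 and 0.01, no filter on low values, a mean FPKM of at least 5, scaling by the median of ratios, rescaling each library to the same total, quantile normalization, limma without a trend, array weights, the tumour number as a replicate block, and each library left out in turn. After seeing the data, 3 more were added: leaving out 429 tested genes of short RNAs, leaving out genes listed at 0 in any library, and rescaling to the same total without the short RNAs. Short RNA genes are microRNA, snoRNA and other genes whose longest transcript is under 200 bases in the GENCODE annotation of GRCm38, which was used for transcript lengths and GC content only. That annotation gave a length for 95.1% of tested genes. No coordinates are reported, because its build differs from mm9. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used for tables and plots.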

Results

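The data were FPKM values of 23940 genes in the CD45-negative fraction of 6 YUMM1.7 melanomas, 3 pre-treatment and 3 residual on BRAF inhibitor. The total FPKM per library ranged from 414834 in on-BRAFi replicate 3 to 921297 in pre-treatment replicate 1. Genes of short RNAs made up between 23.1% and 40.6% of these totals. Between 11074 and 11740 genes reached 1 FPKM in a library. Across the 12075 tested genes, the Spearman correlation was 0.840 to 0.892 between libraries of a group and 0.694 to 0.798 between libraries of different groups. No pair of libraries shared identical values, and the first principal component, with 39.6% of the variance, separated the groups. Means below are given with the SD over the 3 libraries of a group.

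**Figure D1:**
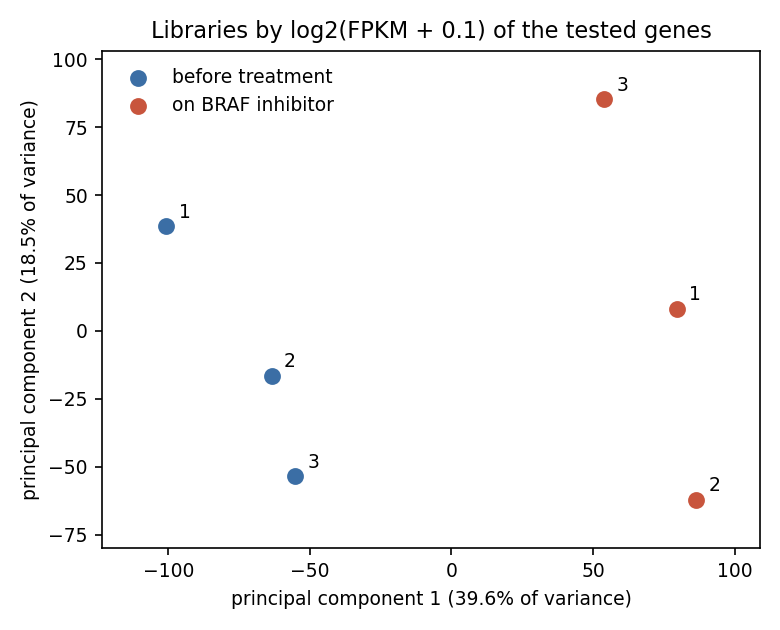
The 6 libraries are placed by the first and second principal components of log2(FPKM + 0.1) over the tested genes, with 39.6% and 18.5% of the variance; points are single libraries, numbered by replicate and coloured by group. The 3 pre-treatment libraries lie on the left and the 3 libraries on BRAF inhibitor on the right of the first component.

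The comparison asks how gene expression in the CD45-negative cells differed between residual tumours on BRAF inhibitor and tumours before treatment. On the inhibitor, genes of mitosis, DNA replication, MAPK pathway output, glycolysis and the integrated stress response were lower as lists, and genes of the extracellular matrix, fibroblasts, vessels and complement were higher. The sorted cells are a mix, so none of the differences below can be assigned to a change within one cell type. A changed mix of cells was examined only for the cell cycle, matrix and fibroblast genes, where it could not be told apart. Ccnd1, which encodes cyclin D1, fell from 71.1 ± 14.6 to 13.8 ± 2.31 FPKM, and Postn, which encodes the matrix protein periostin, rose from 316 ± 84.5 to 7669 ± 613 FPKM. Of the 12075 genes, 2307 changed in limma's test with Benjamini-Hochberg adjustment, 1058 higher and 1249 lower, and 1809 of these changed at least 2-fold. The 3 values of one group all lay above those of the other in 40.4% of tested genes, against 10% by chance for 3 against 3. Of the 32 gene lists tested, 14 passed limma's camera, 6 higher and 8 lower; none of them passed with an estimated correlation, where 5 lists had an unadjusted p under 0.05. Rescaling each library to the same total moved the median of all genes up by 0.54 on the log2 scale and gave 2004 higher and 520 lower genes, so directions are relative to the scaling of the deposited values. Leaving out a single library gave between 1112 and 1552 changed genes, and 103 of the 167 genes named by the rule and past the threshold passed whichever library was left out.

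Cell cycle genes were lower in all 3 treated tumours. The median FPKM over the mitosis list was 21.4 ± 2.20 before treatment and 2.37 ± 0.799 on the inhibitor. Mki67, a marker of cycling cells, fell from 38.6 ± 14.0 to 3.17 ± 1.51 FPKM, a log2 fold change of -3.61 ± 0.41 (SE). Plk1, a kinase of mitotic entry, fell 10.2-fold, and Bub1b, a kinase of the spindle checkpoint, fell 11.1-fold. Cdk1, the main kinase of mitosis, fell from 28.3 ± 6.86 to 4.51 ± 0.0230 FPKM. All 22 genes of the mitosis and G2/M list fell, over all genes tested and adjusted over the list alone, with a median log2 fold change of -3.19 (limma's camera, adjusted p = 5.36e-16; adjusted p = 0.276 with an estimated correlation). Aurka missed the threshold without any 1 pre-treatment library or on-BRAFi replicate 3 (limma, adjusted p up to 0.0988), and Nusap1 without any 1 pre-treatment library or on-BRAFi replicate 1 (up to 0.140).

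Of the 22 genes of DNA replication and the G1/S step, 20 fell, over all genes and adjusted over the list alone, with a median log2 fold change of -2.18. Mcm2 and Mcm6, subunits of the replicative helicase, fell 4.66-fold and 7.18-fold. Uhrf1, which keeps DNA methylation through replication, fell 5.62-fold, and Rrm1, a subunit of ribonucleotide reductase, fell 3.53-fold. The 2 members that did not pass were Ccne1, at 4.11 ± 0.286 and 2.17 ± 1.62 FPKM, and E2f1, at 3.15 ± 1.99 and 2.89 ± 0.861 FPKM. Limma's camera gave adjusted p = 1.02e-10 for the list (adjusted p = 0.276 with an estimated correlation). Of its genes 11 fell without pre-treatment replicate 2, 13 without pre-treatment replicate 3 and 10 without on-BRAFi replicate 1.

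Of the 19 tested genes of MAPK pathway output, a readout of signalling below BRAF, 5 fell and 14 did not pass (8 fell when adjusted over the list alone). Besides Ccnd1, these were the ETS transcription factors Etv4 and Etv5, the AP-1 subunit Fosl1 and the membrane protein Emp1. Etv5 fell from 10.6 ± 2.82 to 1.69 ± 0.393 FPKM, Fosl1 fell 8.62-fold, Etv4 fell 15.2-fold and Emp1 fell 2.79-fold. Dusp6, a phosphatase induced by ERK that switches it off again, was at 36.5 ± 10.3 and 32.9 ± 9.32 FPKM, a log2 fold change of -0.14 with a 95% interval from -0.85 to 0.57. None of the other feedback inhibitors passed: Dusp5, Spry1, Dusp4 and Spred1 had log2 fold changes of -1.97, -1.74, -1.498 and -1.12, and Spry2, Spry4 and Spred2 of -0.46, -0.29 and -0.26. Ier3, Epha2, Phlda1 and Etv1 were at -0.88, -0.84, -0.47 and 0.65 and did not pass either. Egr1, an immediate early target of ERK, was at 377 ± 102 and 466 ± 18.4 FPKM. Fos, from the list of immediate early genes that respond to tissue dissociation, was also high in both groups, at 415 ± 35.0 and 423 ± 79.0 FPKM. An effect of dissociation on Egr1 was not tested. Myc was at 12.2 ± 5.48 and 4.76 ± 0.740 FPKM (limma, adjusted p = 0.0574). The list's median log2 fold change was -1.12 and it passed limma's camera (adjusted p = 0.000320; adjusted p = 0.411 with an estimated correlation). Emp1 missed the threshold when libraries were rescaled to the same total. The sort left tumour cells mixed with other cells, so these values cannot be assigned to signalling in the tumour cells. A change in the mix of cells was not tested for this list.

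Extracellular matrix genes were higher on the inhibitor, and with them markers of fibroblasts. Col1a1 and Col3a1, fibrillar collagens, rose 11.8-fold and 9.07-fold, the latter from 531 ± 103 to 4761 ± 128 FPKM. Postn rose 24.8-fold and Lum, a collagen-binding proteoglycan, rose 12.6-fold. Of the 21 matrix genes, 17 rose and 1 fell, 18 and 1 adjusted over the list alone, with a median log2 fold change of 1.74. The gene that fell was Timp1, an inhibitor of matrix metalloproteinases, from 152 ± 47.3 to 22.3 ± 4.82 FPKM. The members that did not pass were Bgn, Fbn1 and Timp2, with log2 fold changes of 0.23, -0.07 and 1.12. In limma's camera the list had adjusted p = 8.73e-12 (adjusted p = 0.0517 with an estimated correlation).

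Of the 12 fibroblast markers, 4 of which are also on the matrix list, 8 rose and none fell; 9 rose adjusted over the list alone. Dpt, which encodes the dermal matrix protein dermatopontin, rose from 12.9 ± 1.51 to 507 ± 68.9 FPKM, and Dcn, the proteoglycan decorin, rose 7.64-fold. Pdgfra, Fap and Pdpn did not pass, with log2 fold changes of 0.22, 0.01 and -0.41, and Thy1 was at 2.50. The median log2 fold change was 3.06 and the list passed limma's camera (adjusted p = 6.03e-07; adjusted p = 0.276 with an estimated correlation).

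Markers of blood vessels were higher too. Of the 12 tested endothelial markers, 9 rose and none fell, 10 rose adjusted over the list alone, and the median log2 fold change was 1.76. Without pre-treatment replicate 1 or 3 or on-BRAFi replicate 1, 5 rose, and without pre-treatment replicate 2 or on-BRAFi replicate 2 or 3, 4 rose. Cdh5, the cadherin of endothelial junctions, rose from 5.34 ± 0.486 to 16.2 ± 4.87 FPKM. Vwf, the von Willebrand factor gene, rose 5.14-fold and the receptor gene Tek rose 12.9-fold, whereas Eng was at 22.6 ± 7.85 and 23.8 ± 4.06 FPKM. Of 7 pericyte and smooth muscle markers, Rgs5, Tagln and Notch3 rose, Cspg4 fell and 3 did not pass; 6 rose and 1 fell adjusted over the list alone. After rescaling to the same total 5 rose and none fell. Rgs5, a pericyte marker, rose 8.74-fold, and Tagln, an actin-binding protein of smooth muscle, rose 7.25-fold. Both lists passed limma's camera, with adjusted p = 3.09e-05 for endothelial and 0.0125 for pericyte markers (adjusted p = 0.276 for each with an estimated correlation). The pericyte call was lost when only genes of at least 5 FPKM were tested and after rescaling to the same total without short RNAs (adjusted p from 0.00189 to 0.180 over the alternatives). Notch3 missed the threshold without pre-treatment replicate 2 and without on-BRAFi replicate 1 (limma, adjusted p up to 0.0522), and Cspg4 without pre-treatment replicate 1 or 3 or on-BRAFi replicate 1 or 3 (up to 0.0850).

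**Figure D2:**
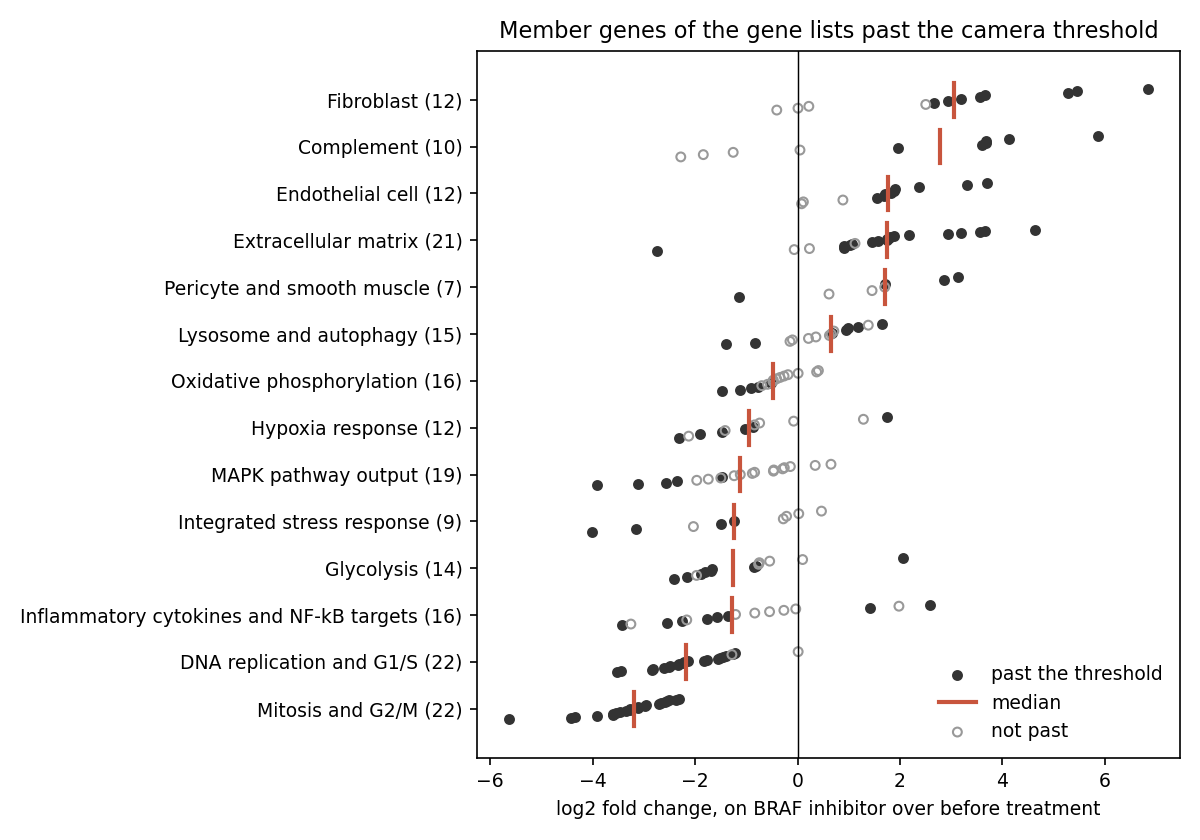
Each point is the log2 fold change of 1 tested gene, on BRAF inhibitor over pre-treatment, in the 14 gene lists that passed limma's camera; numbers in brackets are tested members, filled points passed the threshold over all genes, open points did not, and bars mark medians. Medians run from -3.19 for the mitosis list to 3.06 for the fibroblast list, and the oxidative phosphorylation median turns positive when libraries are rescaled to the same total.

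Genes of the complement system were higher, as were fibroblast markers, with a median log2 fold change of 2.78 over 10 genes. C3, the central component, rose from 2.50 ± 1.64 FPKM to 218, 200 and 55.8 FPKM, and it was lowest in on-BRAFi replicate 3 among the treated libraries, as were C4b and Serping1. C1ra and C1s, the proteases of the first complex, rose 12.1-fold and 12.9-fold, and Serping1, their inhibitor, rose 17.5-fold. In all 6 rose and none fell; adjusted over the list alone, 6 rose and 2 fell. C1qa, C1qb and C1qc, which are also on the macrophage list, did not pass, with log2 fold changes of -1.26, -1.84 and -2.28. The list passed limma's camera (adjusted p = 0.0117; adjusted p = 0.411 with an estimated correlation) but not after rescaling to the same total (adjusted p = 0.0943, in a range of 2.22e-05 to 0.2195 over the alternatives).

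Of 15 lysosome and autophagy genes, 5 rose and 2 fell, 9 and 2 adjusted over the list alone, with a median log2 fold change of 0.66. Ctsd, the protease cathepsin D, rose from 87.0 ± 14.4 to 170 ± 4.59 FPKM, and Hexa, a subunit of lysosomal hexosaminidase, rose 2.27-fold. The genes that fell were Ctsl, the protease cathepsin L, and Sqstm1, a receptor for selective autophagy. After rescaling to the same total 8 genes rose and none fell, and with quantile normalization 5 rose and none fell. Without any 1 library 2 or 3 genes rose and at most 1 fell. Ctsl passed only when on-BRAFi replicate 2 was left out, and Sqstm1 only when on-BRAFi replicate 1 was (limma, adjusted p up to 0.0860 and 0.0724). The list passed limma's camera (adjusted p = 0.0234; adjusted p = 0.276 with an estimated correlation), but not with only genes of at least 5 FPKM or after rescaling to the same total, in a range of 0.00509 to 0.0693.

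Glycolytic genes were lower. Ldha, which converts pyruvate to lactate, fell from 183 ± 15.1 to 52.6 ± 5.48 FPKM, and Pkm, the pyruvate kinase gene, fell 4.44-fold. Gapdh and Pgk1, enzymes of the middle of the pathway, fell 3.18-fold and 3.69-fold. Of 14 genes, 8 fell and 1 rose, 10 and 1 adjusted over the list alone, with a median log2 fold change of -1.26; without on-BRAFi replicate 1 or 3, 5 fell. The gene that rose was Pfkfb3, whose product makes an activator of phosphofructokinase, from 1.30 ± 0.222 to 5.74 ± 1.14 FPKM. Glycolysis genes as a list passed limma's camera (adjusted p = 7.93e-05; adjusted p = 0.316 with an estimated correlation).

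In the integrated stress response list, 4 of 9 genes fell, 5 adjusted over the list alone, with a median log2 fold change of -1.25. The 4 were genes of amino acid synthesis. Asns, asparagine synthetase, fell from 19.1 ± 2.09 to 2.17 ± 0.969 FPKM, and Psat1, of serine synthesis, fell 16.1-fold. Phgdh, the first enzyme of serine synthesis, fell 2.37-fold, and Shmt2, of mitochondrial one-carbon metabolism, fell 2.83-fold. Atf4, the transcription factor of the response, was at 128 ± 23.7 and 129 ± 6.53 FPKM, and Ddit3 was at 24.9 ± 5.95 and 21.5 ± 5.48 FPKM. As a list these genes passed limma's camera (adjusted p = 0.0117; adjusted p = 0.282 with an estimated correlation). Phgdh missed the threshold when libraries were rescaled to the same total.

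Of 12 hypoxia genes, 5 fell and 1 rose, 7 and 1 adjusted over the list alone, with a median log2 fold change of -0.95; without any 1 of the 6 libraries between 0 and 2 fell, none of them without on-BRAFi replicate 1. Bnip3, a mitophagy receptor, was at 95.7 ± 18.3 and 35.3 ± 12.6 FPKM, and Ero1l, an oxidase of the endoplasmic reticulum, fell 4.96-fold. Ndrg1 rose 3.34-fold, whereas Car9 was at 2.07 ± 0.722 and 0.499 ± 0.476 FPKM and did not pass. Bnip3 missed the threshold without pre-treatment replicate 1 or 2 or on-BRAFi replicate 1 or 3, Ero1l without pre-treatment replicate 1 or 2 or on-BRAFi replicate 1, and Ndrg1 without pre-treatment replicate 2 or 3 or on-BRAFi replicate 1 or 2 (limma, adjusted p up to 0.0678, 0.0662 and 0.0825). The list passed limma's camera (adjusted p = 0.0255; adjusted p = 0.411 with an estimated correlation) but not without pre-treatment replicate 1 (adjusted p = 0.0603, in a range of 0.00736 to 0.0603). Of 16 oxidative phosphorylation genes, 5 fell, 8 adjusted over the list alone, among them the cytochrome oxidase subunits Cox4i1 and Cox5a, 2.18-fold and 2.80-fold. Each of these 2 missed the threshold without pre-treatment replicate 1 or 3, Cox4i1 also without on-BRAFi replicate 1 and Cox5a without on-BRAFi replicate 2 or 3 (limma, adjusted p up to 0.0649 and 0.0688), and both after rescaling to the same total. That list's median was -0.48 and it passed limma's camera (adjusted p = 0.00948; adjusted p = 0.385 with an estimated correlation). Without any 1 of the 6 libraries between 0 and 2 of its genes fell, none of them without pre-treatment replicate 3. Its call was lost with quantile normalization and after rescaling to the same total, where the median was 0.07 (adjusted p = 0.156, in a range of 0.000747 to 0.197).

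Several inflammatory genes were lower and a few were higher. Tnfaip3, an inhibitor and target of NF-kB, fell from 140 ± 5.50 to 12.8 ± 0.671 FPKM. The chemokine genes Cxcl1 and Ccl2 fell 5.86-fold and 4.75-fold, Ccl2 from 449 ± 83.9 FPKM. Of 16 genes, 6 fell and 2 rose, 8 and 2 adjusted over the list alone, with a median log2 fold change of -1.29; without on-BRAFi replicate 1, 3 fell. Those that rose were Cxcl12, a chemokine made by stromal cells, 2.65-fold, and Icam1, an adhesion molecule, 6.02-fold. Il6 was at 6.09 ± 5.04 and 18.2 ± 14.2 FPKM and did not pass. The list passed limma's camera (adjusted p = 0.0117; adjusted p = 0.411 with an estimated correlation) but not without pre-treatment replicate 3 (adjusted p = 0.0534, in a range of 0.000813 to 0.0534).

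Several immune lists did not pass limma's camera. In the type I interferon response, 2 of 19 genes fell, 1 adjusted over the list alone (adjusted p = 0.608). The list's median log2 fold change was 0.06 and its mean -0.20, and camera's direction was lower. The genes were Cxcl10, an interferon-induced chemokine, from 93.7 ± 38.9 to 21.6 ± 9.95 FPKM, and Irf7, a transcription factor, from 16.2 ± 1.06 to 10.5 ± 0.726 FPKM. Neither passed after rescaling to the same total. Irf7 missed the threshold without any 1 of the 6 libraries and Cxcl10 without pre-treatment replicate 2 or 3 or on-BRAFi replicate 2 or 3 (limma, adjusted p up to 0.0897 and 0.0637). No gene of MHC class I (12 tested) or class II (4 tested) antigen presentation passed limma's test, over all genes or over the list alone. Their medians were 0.09 and 0.01 (limma's camera, adjusted p = 0.608 and 0.902). The MHC class I list passed camera as higher without pre-treatment replicate 3 (adjusted p = 0.0364, in a range up to 0.989). After rescaling to the same total 1 class I gene rose, and 3 did when that total left out short RNAs, with none falling. Of 8 checkpoint ligands, Lgals9 and Cd276 rose 3.68-fold and 3.12-fold and Lgals3 and Pvr fell 3.17-fold and 2.14-fold, 2 and 2 also over the list alone (limma's camera, adjusted p = 0.508). After rescaling to the same total 3 of these genes rose and none fell, and both Lgals3 and Pvr missed the threshold. Pvr passed without a library only where that was pre-treatment replicate 2 (limma, adjusted p up to 0.102).

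Lineage lists did not pass either. Of 18 melanocyte pigmentation genes, 4 were high enough to test; Mitf, the melanocyte transcription factor, rose from 5.77 ± 1.40 to 21.5 ± 2.16 FPKM, and it alone passed over the list alone. Tyr, Kit and Slc24a5 had log2 fold changes of 0.40, 0.88 and -0.02. Tyrp1, Dct and Mlana were listed at 0 in all 6 libraries, and mean Sox10 was 0.0245 and 0.0658 FPKM; these 4 genes were named after their values were seen. Of 7 neural crest genes, the water channel gene Aqp1 fell 2.11-fold and Tfap2b, a neural crest transcription factor, rose 1.64-fold, 1 and 1 also over the list alone. Tfap2b passed without a library only where that was on-BRAFi replicate 2 (limma, adjusted p up to 0.108), and Aqp1 missed the threshold with quantile normalization and after rescaling to the same total, where 2 neural crest genes rose and none fell. Of 17 mesenchymal genes, 2 rose and 3 fell, 3 and 4 adjusted over the list alone, and 5 rose and none fell after rescaling to the same total. Vim, the intermediate filament vimentin, fell from 1589 ± 95.5 to 711 ± 29.6 FPKM, although not with quantile normalization or after rescaling to the same total, and Nt5e, an ectonucleotidase, rose 5.05-fold. Without on-BRAFi replicate 1 or 3, 1 of the mesenchymal genes rose and 1 fell; 1 rose without pre-treatment replicate 2, and 1 fell without pre-treatment replicate 1 or 3. Limma's camera gave adjusted p = 0.174, 0.999 and 0.921 for the pigmentation, neural crest and mesenchymal lists. The neural crest list had a median of -0.11 and a mean of -0.02 with camera's direction higher, and the mesenchymal list a median of -0.03 and a mean of 0.09.

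Several growth factor and receptor genes were higher, although neither list passed limma's camera. Igf1, insulin-like growth factor, rose from 4.38 ± 2.38 to 96.2 ± 4.35 FPKM, and Pdgfd and Fgf7 rose 3.28-fold and 2.58-fold. Areg, a ligand of the EGF receptor, fell from 7.25 ± 4.41 to 0.372 ± 0.0403 FPKM. Of 15 ligands, 6 rose and 3 fell, 9 and 3 adjusted over the list alone, and the median was 0.93; after rescaling to the same total 9 rose and 1 fell (limma's camera, adjusted p = 0.0559). Of the ligands, 3 rose without pre-treatment replicate 3 or on-BRAFi replicate 1 or 2, and 1 fell without any 1 library. The growth factor ligand list passed limma's camera with only genes of at least 5 FPKM (adjusted p = 0.0108), with array weights (0.0458), without genes listed at 0 (0.0469) and without on-BRAFi replicate 3 (0.0496), in a range of 0.0108 to 0.331. The receptor tyrosine kinase list passed limma's camera with no filter (adjusted p = 0.0200), with quantile normalization (0.0393) and without on-BRAFi replicate 3 (0.0496), in a range of 0.0200 to 0.358. Egfr, the EGF receptor, rose from 4.92 ± 1.94 to 20.6 ± 5.17 FPKM, and Ddr2, a collagen receptor, rose 1.95-fold. Of 15 receptor tyrosine kinases, 4 rose and none fell, 4 and 1 adjusted over the list alone, with a median of 0.48 (limma's camera, adjusted p = 0.0582). Egfr missed the threshold without on-BRAFi replicate 1 (limma, adjusted p = 0.0517), and the others that rose, Kdr and Ddr1, without any 1 of the 6 libraries (up to 0.102 and 0.151). Kdr is also an endothelial marker, a list that rose. After rescaling to the same total 5 receptor tyrosine kinases rose, and 9 did when that total left out short RNAs, with none falling in either.

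**Figure D3:**
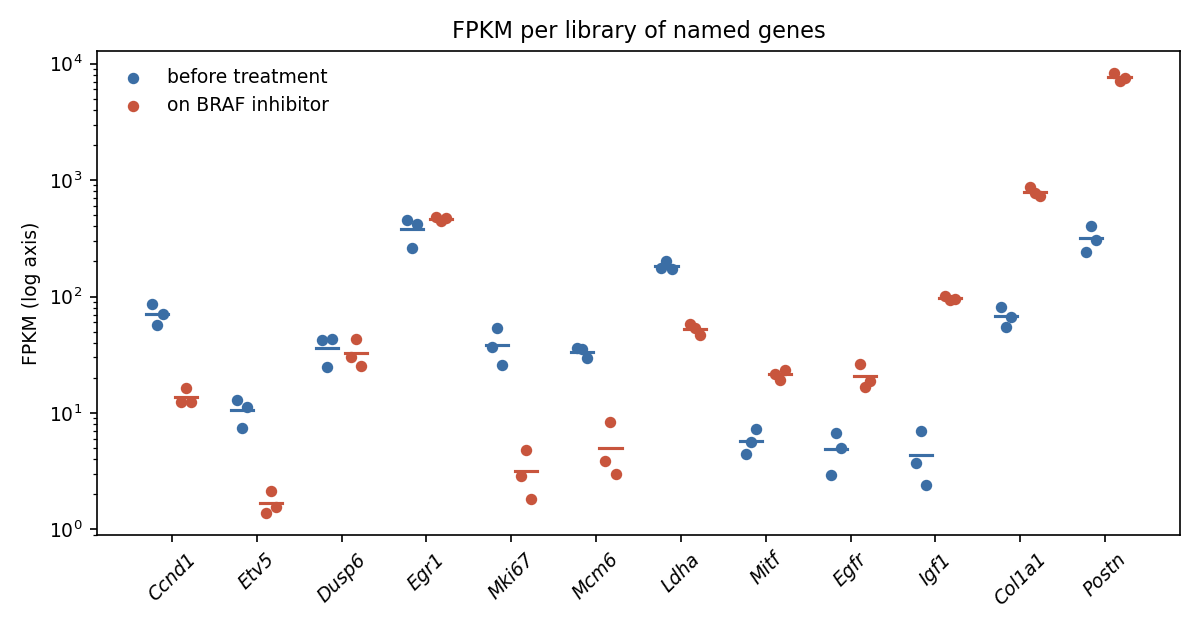
FPKM on a log axis of 12 named genes in each library, with points for the 3 libraries of a group and bars for their mean, pre-treatment in blue and on BRAF inhibitor in red. The groups do not overlap for Ccnd1, Etv5, Mki67, Mcm6, Ldha, Mitf, Egfr, Igf1, Col1a1 and Postn, and they overlap for Dusp6 and Egr1.

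Among 10 BCL2 family genes, Bmf, which promotes apoptosis, rose 2.92-fold, and Pmaip1, which encodes NOXA, fell from 6.67 ± 2.09 to 1.60 ± 0.587 FPKM, 1 and 1 also over the list alone (limma's camera, adjusted p = 0.900). Bmf missed the threshold without on-BRAFi replicate 1, and Pmaip1 without pre-treatment replicate 1 or 3 or on-BRAFi replicate 2 (limma, adjusted p up to 0.0577 and 0.05998). Of the BCL2 family genes, 1 rose and 1 fell after rescaling to the same total, and 5 rose and 1 fell when that total left out short RNAs. Of 11 TGF-beta and YAP targets, 2 fell, among them Tgfbi, a secreted matrix protein induced by TGF-beta, 1.69-fold, and 1 rose and 3 fell adjusted over the list alone (limma's camera, adjusted p = 0.608). After rescaling to the same total 2 of these targets rose and none fell, and Tgfbi missed the threshold under every other scaling. Tgfbi passed without a library only where that was on-BRAFi replicate 2 (limma, adjusted p up to 0.129). Of 5 WNT targets, Axin2, a feedback inhibitor of the pathway, rose 2.90-fold and it alone passed over the list alone (limma's camera, adjusted p = 0.756); it passed without a library only where that was pre-treatment replicate 3 (limma, adjusted p up to 0.0783).

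Some leukocyte genes were measured in the sorted cells. Ptprc, the gene of the sorted marker, was at 1.29 ± 0.806 and 0.677 ± 0.505 FPKM, below the filter for testing. Of 4 pan-leukocyte and 10 macrophage markers none passed limma's test, over all genes or over the list alone, with medians of -0.68 and -1.55 (camera adjusted p = 0.442 and 0.0582). The macrophage and dendritic cell list passed limma's camera as lower after rescaling to the same total (adjusted p = 0.00986), with quantile normalization, with a pseudocount of 1, with no filter and without on-BRAFi replicate 1 (adjusted p = 0.00601) or 3 (0.0496), in a range of 0.00379 to 0.201. The pan-leukocyte list passed with no filter (adjusted p = 0.0420, in a range of 0.0420 to 0.777). Lyz2, a macrophage lysozyme, was at 13.2 ± 0.480 and 14.2 ± 11.7 FPKM, Cd68, a macrophage lysosomal protein, at 10.2 ± 1.94 and 12.1 ± 8.63 FPKM, and Fcer1g was at 3.43 ± 0.732 and 0.646 ± 0.742 FPKM. Of 3 T and NK cell markers none passed over all genes, and Thy1, shared with the fibroblast list, rose over the list alone (limma's camera, adjusted p = 0.608). None of 4 Schwann cell and 5 erythroid markers passed limma's test, over all genes or over the list alone (camera adjusted p = 0.608 and 0.138); the erythroid list passed as higher without on-BRAFi replicate 3 (adjusted p = 6.95e-04, in a range up to 0.601). The haemoglobin gene Hba-a2 was at 813 and 663 FPKM in on-BRAFi replicates 1 and 2, at 84.9 in on-BRAFi replicate 3, and at 71.1 to 176 before treatment; it has a near-identical copy, so its values are uncertain. B cell, neutrophil and keratinocyte lists had 1 tested gene each and none changed, and skeletal muscle had 2 and none changed. Of the adipocyte list 2 genes were tested, and both rose: Fabp4, a fatty acid carrier also found in capillaries, from 2.32 to 73.6 FPKM, and Lpl, lipoprotein lipase, from 0.552 to 11.6 FPKM; these 2 were not followed through the alternatives.

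Of the 12 genes that respond to tissue dissociation, Zfp36 fell 1.72-fold over all genes and none passed over the list alone (limma's camera, adjusted p = 0.189), and Fos was at 415 ± 35.0 and 423 ± 79.0 FPKM. The list's median was -0.44, and 0.11 after rescaling to the same total; Zfp36 passed without a library only where that was pre-treatment replicate 2 (limma, adjusted p up to 0.106). Of the single genes fixed for naming, Braf was at 1.86 ± 1.52 and 0.784 ± 0.702 FPKM and Cdkn2a at 8.50 ± 2.57 and 4.25 ± 1.12 FPKM, and neither passed limma's test. Map2k1, the kinase MEK1 below BRAF, fell from 10.2 ± 1.89 to 5.43 ± 1.12 FPKM (limma, adjusted p = 0.0427) but missed the threshold without any 1 of the 6 libraries (limma, adjusted p up to 0.121).

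The 8 largest increases that met the naming rule were in Angptl1, Clec3b, Cxcl13, C7, Cd55, Tnxb, Cpz and Fmod. Angptl1, an angiopoietin-like secreted protein, rose from 0.588, 3.26 and 0.755 FPKM to 136, 164 and 152 FPKM (limma, adjusted p = 0.00110), and Tnxb, the matrix protein tenascin-X, rose from 0.0801 ± 0.0102 to 15.0 ± 4.75 FPKM. Clec3b was at 15.8, 14.8 and 11.6 FPKM on the inhibitor and at most 0.0383 before, Cd55 at 25.9, 17.4 and 6.32 against at most 0.303, Cpz at 12.4, 7.82 and 15.8 against at most 0.0896, and Fmod at 11.2, 6.84 and 13.7 against at most 0.158. Cxcl13 and C7 were listed at 0 in all 3 pre-treatment libraries, so no fold is given; C7 was at 21.8, 20.9 and 1.60 FPKM on the inhibitor and Cxcl13 at 12.8, 20.1 and 3.97 FPKM.

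The 8 largest decreases that met the naming rule were in Pbk, Bub1, Cenpw, Dmp1, Hao1, Klra18, Klra33 and Hist1h2aa, the first 3 of them cell cycle genes. Dmp1, a secreted protein of bone matrix, fell from 56.9 ± 9.69 to 1.19 ± 0.0758 FPKM (limma, adjusted p = 7.24e-05). Pbk, a mitotic kinase, was at 24.1, 20.8 and 37.2 FPKM before treatment and at most 0.502 on the inhibitor, and Bub1, of the spindle checkpoint, at 17.6, 19.5 and 20.8 against at most 1.00. Cenpw, of the centromere, was at 35.1, 24.1 and 28.0 FPKM against at most 3.27, and it missed the threshold without any 1 pre-treatment library or without on-BRAFi replicate 3 (limma, adjusted p up to 0.0801). Hao1, hydroxyacid oxidase, was at 6.97, 4.36 and 7.53 FPKM against at most 0.200. Klra18 and Klra33, of the Ly49 receptor family, and the histone gene Hist1h2aa, listed at 0 in all 3 treated libraries, have close paralogs, so their values are uncertain. Klra18 passed without a library only where that was on-BRAFi replicate 1, and Klra33 only where it was on-BRAFi replicate 2 or 3 (limma, adjusted p up to 0.0917 and 0.0901).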

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

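Of 5968 genes with some value above 0 that were too low to be tested, short RNAs left out, 32 were listed at 0 in all 3 pre-treatment libraries and at 0.3 FPKM or more in all 3 libraries on BRAF inhibitor. They were picked out because they lie outside the tested genes; the selection itself sets the treated values above the untreated ones, and how many such genes chance would give was not tested. The reverse held for 13 genes. Wnt2, a secreted signalling protein, was at 0.868, 1.23 and 0.495 FPKM on the inhibitor, C1qtnf2 at 0.939, 1.24 and 1.21, and Slc1a3, a glutamate transporter, at 1.34, 0.567 and 1.91. Of the genes listed at 0 on the inhibitor, Cd48, a leukocyte surface protein, was at 0.543, 1.17 and 1.36 FPKM before treatment, and Clec12a, a receptor of myeloid cells, at 0.515, 1.704 and 1.32. These 5 genes were named after their values were seen, and no test was run on them. Exact zeros in this table are not taken as a reading of absence, since read depth is unknown. Genes classed here as short RNAs aside, 7 tested genes with a mean of at least 20 FPKM were listed at 0 in some library. Some owed that mean to 1 library, as Nkain2 did, at 127 FPKM in on-BRAFi replicate 3 and at most 0.380 elsewhere. Lta did not: it was at 834.5 and 593.2 FPKM in pre-treatment replicates 1 and 2 and listed at 0 in pre-treatment replicate 3. On the inhibitor it was at 104.5 FPKM in replicate 2 and listed at 0 in replicates 1 and 3. A 0 beside high values in the same group may be unreliable, and with read depth unknown these genes cannot settle whether a 0 hides expression.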

How the results depend on the processing

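The short RNA and zero-value alternatives were chosen after seeing the data. Rescaling to the same total gave 2004 genes higher and 520 lower, and without short RNAs 4496 changed, 3816 higher, 680 lower and 3197 at least 2-fold; both shift all genes upward (median 0.54 and 0.60), which their construction explains. Under these 2 settings the oxidative phosphorylation median turned to 0.0679 and 0.121 and Uqcrc2, of respiratory complex III, to 0.0192 and 0.073. Without 1 library there were 1112 to 1552 changed genes, 483 to 767 higher, 629 to 887 lower and 1038 to 1372 at least 2-fold, with fewer samples in each fit. The changed genes numbered 1534, 1398 and 1552 without pre-treatment replicates 1, 2 and 3, and 1112, 1482 and 1457 without on-BRAFi replicates 1, 2 and 3. None of the 14 lists past the threshold passed camera with an estimated correlation (0 lists), and all 14 passed fry. Fry also passed 4 lists that camera did not, receptor tyrosine kinases (adjusted p = 2.20e-04), growth factor ligands (0.00148), pigmentation (0.0160) and checkpoint ligands (0.0285), all as higher, 18 lists in all. The replicate block aside, the other alternatives stayed within 1.5 times of the counts of changed, higher, lower and at least 2-fold genes and of lists; counts of changed members within lists moved by more than that in 234 comparisons. Among lists, 11 comparisons lost a call, 3 of them for oxidative phosphorylation, and 17 gained one; no call changed sign and stayed past the threshold in any setting. Of the 167 named genes past the threshold, 96 passed in every setting apart from the replicate block, and 32 were lost after rescaling to the same total. Among uncalled results, the sign changed in 140 comparisons of a named gene and 40 of a list. No sign of pairing by tumour number was seen, which 3 libraries per group cannot exclude. Same-numbered libraries deviated with correlations of -0.03, 0.01 and -0.09, and differently numbered ones with correlations from -0.09 to 0.12. With the number as a block, 1237 genes changed, 500 higher and 737 lower, 1197 at least 2-fold, in a fit with fewer degrees of freedom. Read depth is unknown, so what it limits cannot be stated. In simulations with 200 changed genes, 11.2% of 2-fold changes were called. The data gave 2307 changed genes and so a less strict adjustment, and that share is not the sensitivity of this comparison.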

Other observations

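The tests of dilution, tumour-cell share, library scaling and transcript length were chosen after the results they bear on had been seen; the count of other splits was fixed beforehand. The ribosomal protein and histone genes were grouped after their values were seen. Of 77 tested ribosomal protein genes, 74 were lower on BRAF inhibitor past limma's threshold and none higher, with a median log2 fold change of -1.69. The median FPKM over these genes was 1179 ± 236 (SD, n = 3) before treatment and 375 ± 59.6 on the inhibitor. Rps24 was at 5062 and 1655 FPKM and Rpl13a at 3331 and 824 FPKM. Many of these genes have processed pseudogenes, so single values are uncertain. Of 50 tested histone genes, 44 were lower and none higher, with a median of -3.76. Most messages of replication histones lack a poly(A) tail and the family is closely related in sequence, so single histone genes are uncertain.

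Cell cycle genes were lower on the inhibitor. The scalings tried moved all genes by a median of at most 0.60, too little to be the whole cause of a mitosis median of -3.19. That median stayed at -2.63 or below under each of them, and a scaling not tried is not covered. Across transcript lengths the median of genes ran only from -0.54 in the shortest eighth to 0.17 in the longest. After the trend of fold change with length was removed, the mitosis median was -3.19. Dilution of tumour RNA by cells that do not cycle cannot be told apart from fewer cycling cells. The 4 tested pigmentation genes had a median of 0.64, but Sox10 was near 0, so that list is not shown to mark the tumour cells. By the bound first set for this test that median counted against dilution; the condition on Sox10 was added after both values were seen.

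Matrix and fibroblast genes were higher. The matrix median was 1.74 with the deposited values and 1.74 to 2.34 under the other scalings. None of these moved genes down as a whole, so they could not show whether scaling raised this list. Against transcript length as the whole cause, the matrix median was 1.68 after the trend was removed. A lower share of tumour cells, which would raise the markers of the other cell types alike, cannot be told apart from a change within fibroblasts or tumour cells. The fibroblast list, which shares 4 genes with the matrix list, exceeded the endothelial list by 1.24 in mean log2 fold change. Its 95% interval over their genes ran from -0.28 to 2.77, too wide to decide. That interval takes genes as independent, although correlations of 0.19 and 0.22 were estimated within the 2 lists, and it holds no spread between tumours. This interval replaced a comparison with the spread of single genes, by which the lower share had been kept as fitting, after the difference was seen.

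Ribosomal protein genes were lower. Short transcripts were lower in general, with a median of -0.54 in the shortest eighth of genes and 0.17 in the longest. Ribosomal protein genes still lay 1.32 below other genes of the same longest transcript length (difference -1.32, 95% bootstrap interval over genes -1.42 to -1.17). That interval holds no spread between tumours. The longest transcript need not be the one expressed (Rps15a was taken as 5179 bases and Rpl36 as 383), so the match cannot settle length. The ribosomal protein median of -1.69 was below the -0.54 of the shortest eighth. Under every scaling tried that median was -0.96 or below, which argues against these scalings as the whole cause. The treatment may be linked to lower ribosomal protein expression, as a hypothesis; a different mix of cells was not tested.

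The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 2307 changed genes, no other split gave as many (1 of the 10, the real one included), and the highest of the others gave 8. Each other split mixes the 2 groups on both sides, so any difference between the groups adds to its spread. Those counts are therefore not a number of false calls to expect.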
